A study of Arabidopsis thaliana with 6 samples.

How the data were processed

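Per the labels' protocols, rosette RNA was purified on kit columns, turned into cDNA and amplified as RNA with T7 polymerase. The amplified RNA was copied into cDNA that was coupled to Cy3 or Cy5 through amino-allyl groups. The arrays were spotted with Arabidopsis ESTs by the Keck resource at Yale, per the labels. The deposited scanner files hold, per the file headers, the output of QuantArray: an intensity and a local background for each spot and each of 2 channels on the scanner's linear scale, quantified by its histogram method, with no background subtraction. Channel 2 of the deposited files is an intensity of the same kind. The authors also deposited a table of log2 ratios. Set against the scanner values, this table is the log2 of channel 2 over channel 1 in the order of each scanner file, after a normalization. Over spots bright in both channels, its difference from the unnormalized ratio correlated with brightness at -0.99 on replica 1 and at 0.06 on replica 5. The tool is not given in the sources used here. Its columns have a median of 0.0144 (replicas 1 and 6) or -0.0589 (replicas 2 to 5), and what it was centred on stays unknown. It correlated across spots at 0.97 to 1.00 with the ratios computed here and was used only as an alternative.

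Ratios were computed from the scanner intensities with limma 3.58.1 in R 4.3.3. Background was corrected by the normexp method with an offset of 50. The local background was 0 for 76.2% to 96.5% of the spot values. Each array was normalized by global loess, with blank spots given no weight, and there was no scaling between arrays. The 9 spots that the scanner software set to be ignored, all on replica 6, were left out. The file of replica 6 holds no spot names. Its spots were named by their number, and their brightness correlated at 0.93 with that of the same spots on replica 1. Blank spots and 13 spots without a name were left out, and the 26 clones with 2 spots were averaged. Between such spots the mean same-day ratios correlated at 0.59 and differed by a median of 0.29 on the log2 scale.

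Each log2 ratio was turned to SAS1-HA over untransformed by the dyes in the labels. For each clone a model with the difference between the lines and a dye term was fitted by lmFit and eBayes, with Benjamini-Hochberg adjustment over all clones and a threshold of 0.05. A clone needed values on 2 arrays of each dye orientation. The fit over all 6 arrays was set before the data were examined. The fit to the 4 same-day arrays, the fit with replica 1 turned, the averaging of dye-swapped pairs and the filter on blank spots were added after seeing the data. In dye-swapped pairs, replicas 2 and 4 share a tag in their image names, as do 3 and 5. Nothing says whether a tag marks plants, RNA or labelling.

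The rule for clones given by name was the 10 largest rises and falls among those past the threshold with one sign on each array, and otherwise those of smallest p. Without gene names this was limited to 2 per direction: the clone of smallest p in each direction over 6 arrays, the largest same-day fall, and 1 rise chosen after its values were seen. The gene table used here pairs locus tags and RefSeq transcripts with symbols, and no clone identifier matched it, so gene lists and serpin genes were not analysed here.

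The fits were tested on simulated data with 200 of 11926 clones changed, equally on each array, and with each clone's spread as moderated by limma. Arrays were drawn as independent, whereas the real ones correlated at 0.71 within a scan day. The shares recovered and the shares of false calls therefore hold only for such data, and each rests on 1 simulated data set. They do not say what the real 6-array fit could find, nor what share of the real same-day calls is false. For 6 arrays, 80.5% of clones changed by 1 on the log2 scale and 100% of those changed by 2 were recovered, with 2.4% and 4.3% of the calls false. For the same-day arrays, 99.5% and 100% were recovered, with 9.1% and 7.4% of the calls false, above the nominal share. Alternatives covered background correction, normalization, the authors' table, ignored spots, filters on dim clones, the dye term, array weights, scan day as a random block (statmod 1.5.0), a minimum of 2-fold, and leaving out each array.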

Results

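Gene expression was compared between Arabidopsis thaliana plants that overexpress SAS1, a serpin, as a fusion named SAS1-HA and untransformed plants. Serpins are a family of proteins best known as inhibitors of proteases, and the title of the series places SAS1 in the crosstalk between hormones in plant defense. The question put to the data was which transcripts of the rosette differ between the lines. RNA came from rosettes 3 to 4 weeks old. Each of 6 spotted cDNA arrays carried both lines, 1 in Cy3 and 1 in Cy5, and per the labels SAS1-HA was in Cy5 on replicas 2, 3 and 6 and in Cy3 on replicas 1, 4 and 5. An array was printed in 32 blocks, with 323 blank spots and 11952 spots that carried a named clone, for 11926 different clones of expressed sequence tags (ESTs). The labels speak of 2 independent biological experiments without saying which array belongs to which, so the p-values measure the spread between arrays, which may be partly technical.

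The clones are named only by EST identifiers, and 0 of them matched the gene table used here. The files do not pair the clones with genes. No gene can therefore be named, the serpin genes could not be looked up to check the labels, and the groups of defense, hormone and protease genes set up for the comparison were not tested. At most 2 clones per direction are given by their identifiers.

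Signal stood well above the blank spots on each array. The median spot intensity lay between 1436 and 2128 for SAS1-HA and between 1196 and 2641 for the untransformed plants. The share of clones above the 95th percentile of the array's blank spots was 93.2% to 97.8% for SAS1-HA and 91.4% to 98.5% for the untransformed plants, lowest in both lines on replica 6. The headers of the scanner files put replicas 2, 3, 4 and 5 on one scanning day, and replicas 1 and 6 on 2 earlier days of their own. The first 4 are called the same-day arrays here and replicas 1 and 6 the earlier arrays. Each earlier day holds 1 array, so no test could be made within it. The number of arrays limits the precision of each ratio.

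Many clones differed between SAS1-HA and untransformed RNA on the same-day arrays. Of 11926 clones, 5873 (49.2%) passed an adjusted p of 0.05 in limma, 2972 of them higher and 2901 lower in SAS1-HA. Among these, 1503 differed at least 2-fold, with 980 higher and 523 lower. Over all 11926 clones, 53.5% had one sign on 4 of 4 arrays, where 12.5% comes from chance if the arrays are independent. The median standard error of a log2 ratio was 0.11. With each dye-swapped pair averaged to 1 value (replicas 2 and 4, and 3 and 5, paired by a tag in the image names), 4966 clones passed. Nothing in the sources used here says whether these 4 arrays hold 1 or 2 pairs of RNA extracts. With 1 pair they are technical repeats of 1 comparison, and their p-values say nothing of other plants. With the authors' log2 ratios, 2694 clones were higher and 3240 lower, and at least 2-fold 922 were higher and 708 lower.

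The same comparison over all 6 arrays, with the dyes as labelled, gave no clone past the threshold. The smallest adjusted p from limma was 0.116, while 3168 clones had an unadjusted p under 0.05 (1767 higher and 1401 lower), against 596 from chance alone if the arrays are independent. With scan day as a random block the correlation within a day was 0.71, and only the same-day arrays share a day. In that limma fit 192 clones had an unadjusted p under 0.05, fewer than the 596 from chance alone, so the fit may be too strict. The smallest adjusted p over all clones was 0.9996, so this value says nothing particular about any 1 clone. Without replica 1 the count was 2497, without replica 6 it was 2556, and with array quality weights, which gave both the lowest weights, it was 6719. The same-day arrays had weights of 1.34 to 4.4, so the 6719 rests mainly on them and is not separate from the same-day fit. The direction of replica 1 is not settled. Its label puts SAS1-HA in Cy3, but the order of the dyes in its scanner file is the reverse of the order in its label, unlike on the other 5 arrays, and both of its image names carry the letters HA. With the sign of replica 1 turned, 2415 clones passed over 6 arrays, 1393 higher and 1022 lower. Of these, 817 differed at least 2-fold (592 higher and 225 lower), and 2407 also passed on the same-day arrays with the same sign. The same-day arrays are part of this fit, so the overlap is no independent check.

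The same-day arrays stood apart from replicas 1 and 6, which were scanned on different days and yet shared Cy5/Cy3 ratios. Among the same-day arrays the turned log2 ratios correlated across clones at 0.84 to 0.85 in pairs with the same dye orientation and at 0.71 to 0.82 in pairs with opposite orientation. The means of the dye-swapped pairs correlated at 0.88. Between replicas 1 and 6 the correlation was -0.65 with the dyes as labelled, so their Cy5/Cy3 ratios correlated at 0.65. Between a same-day and an earlier array it lay between -0.14 and 0.10. The mean of replicas 1 and 6 as labelled correlated at -0.02 with the same-day mean, and at 0.07 with replica 1 turned. Clones are not independent replicates, and these 15 correlations between arrays and 3 between means are given without a test.

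**Figure D1:**
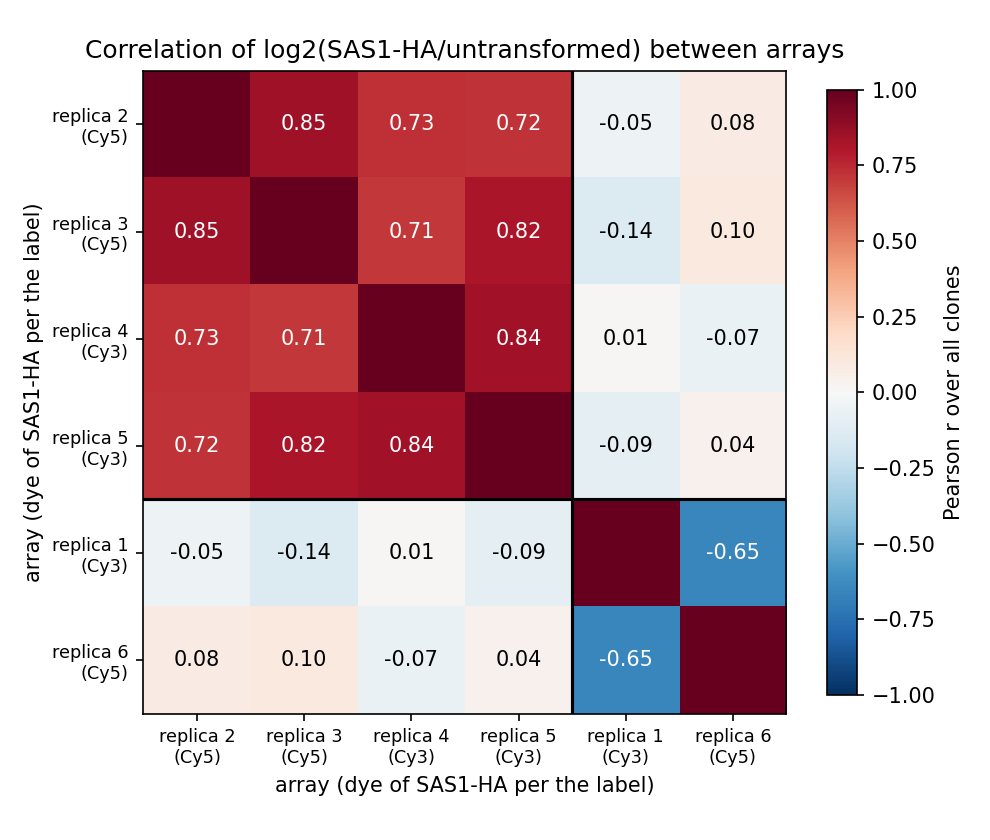
Pearson correlation across clones of log2(SAS1-HA/untransformed), turned by the labelled dyes, for each pair of the 6 arrays, with the dye of SAS1-HA in brackets and black lines parting the same-day arrays from replicas 1 and 6. The same-day arrays correlate at 0.71 to 0.85 with each other, replicas 1 and 6 at -0.65, and pairs across the lines at -0.14 to 0.10.

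Large changes were spread unevenly between the directions. On the same-day arrays 228 clones rose at least 4-fold in SAS1-HA and 50 fell at least 4-fold. At 8-fold and more the balance turned, with 3 rises and 12 falls, and 1 clone fell at least 16-fold. The 10 largest rises with one sign on 4 of 4 arrays had log2 ratios of 2.85 to 3.38, and the 10 largest falls -3.09 to -4.07, with standard errors up to 0.28 and adjusted p from limma up to 2.26e-04. Rises at least 2-fold were 65.2% of the clones changed that much (56.6% in the authors' table), and this share went with brightness. With the clones in 5 equal groups by brightness, 38 rose and 53 fell at least 2-fold in the dimmest group, and 471 rose and 186 fell in the brightest. Altogether 3.8% of the dimmest and 27.5% of the brightest group changed at least 2-fold.

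**Figure D2:**
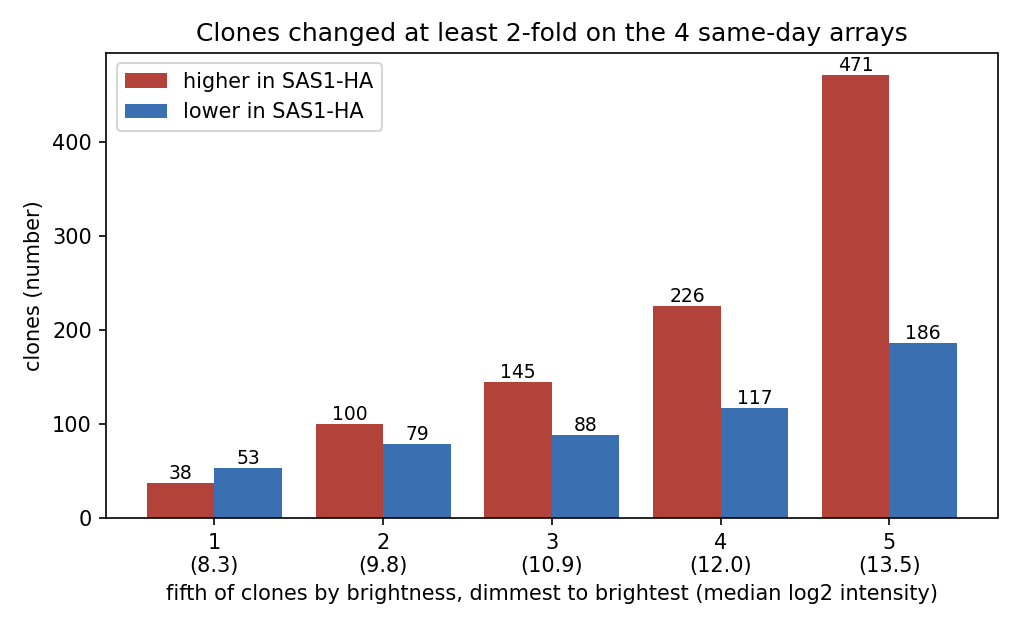
Number of clones past the threshold and changed at least 2-fold on the 4 same-day arrays (vertical axis), higher (red) or lower (blue) in SAS1-HA, for 5 equal groups of clones from dimmest to brightest (horizontal axis), with each group's median log2 intensity in brackets. The brightest group holds 471 rises and 186 falls, the dimmest 38 rises and 53 falls. Brightness averages both lines, so a clone's own change moves it.

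Nearly all clones gave signal in both lines. On 4 of 4 same-day arrays 11221 clones (94.1%) were above the blank spots in both lines, and 29 were above them in neither line on any of the 4. No clone was above the blank spots in SAS1-HA on 4 of 4 arrays and in the untransformed plants on none, and 1 clone was so in the opposite direction.

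The largest fall belonged to EST clone N96898. Its log2 ratio on the same-day arrays was -4.07 ± 0.48 (SD, n = 4), 16.8-fold lower in SAS1-HA, with a standard error of 0.19 and an adjusted p of 3.51e-05 in limma. The size of this fall depends on the processing, at -4.49 without background correction and -4.71 with the authors' log2 ratios. Its median intensity on these arrays was 136 in SAS1-HA and 4224 in the untransformed plants. On replica 6 its log2 ratio was -2.72, and on replica 1 it was 1.81 as labelled. Over 6 arrays as labelled it was -2.86 with a standard error of 0.72 and an adjusted p of 0.116, with replica 1 turned -3.60 with an adjusted p of 0.0042, and without replica 1 -3.83 with an adjusted p of 0.0048. With scan day as a random block it was -1.86 with an adjusted p of 0.9996. R65473, chosen after its values were seen, rose by 2.46 ± 0.24 (SD, n = 4) on the same-day arrays, 5.5-fold, with an adjusted p of 3.74e-05 in limma. Its log2 ratio was 3.86 on replica 6 and -3.25 on replica 1 as labelled, and 1.74 over the 6 arrays with an adjusted p of 0.173. With replica 1 turned it was 2.76 with an adjusted p of 0.0028, and without replica 1 it was 2.71 with an adjusted p of 0.0096. Without any other single array it did not pass, with adjusted p of 0.247 to 0.460, and with scan day as a random block it was 1.15 with an adjusted p of 0.9996.

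With 6 arrays as labelled, the clone with the smallest p among the higher ones was T45440 and among the lower ones H37600, and neither passed, each with an adjusted p of 0.116 in limma. T45440 had a log2 ratio of 1.07 ± 0.54 (SD, n = 6) and was higher in SAS1-HA on 6 of 6 arrays, or 5 of 6 with replica 1 turned. H37600 had a log2 ratio of -0.97 ± 0.70 (SD, n = 6) and was lower on 6 of 6 arrays, or 5 of 6 with replica 1 turned. It was above the blank spots on only 4 of 6 arrays in SAS1-HA and on 5 of 6 in the untransformed plants, so the size of its ratio is uncertain. On the same-day arrays T45440 was at 1.33 ± 0.42 (SD, n = 4) with an adjusted p of 2.23e-04, and H37600 at -0.90 ± 0.42 (SD, n = 4) with an adjusted p of 5.58e-04. With replica 1 turned, T45440 had an adjusted p of 0.0284 and H37600 an adjusted p of 0.0718. Both passed without replica 1 (adjusted p of 0.0156 and 0.0173) and without replica 6 (0.0211 for each), and with scan day as a random block each had an adjusted p of 0.9996.

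**Figure D3:**
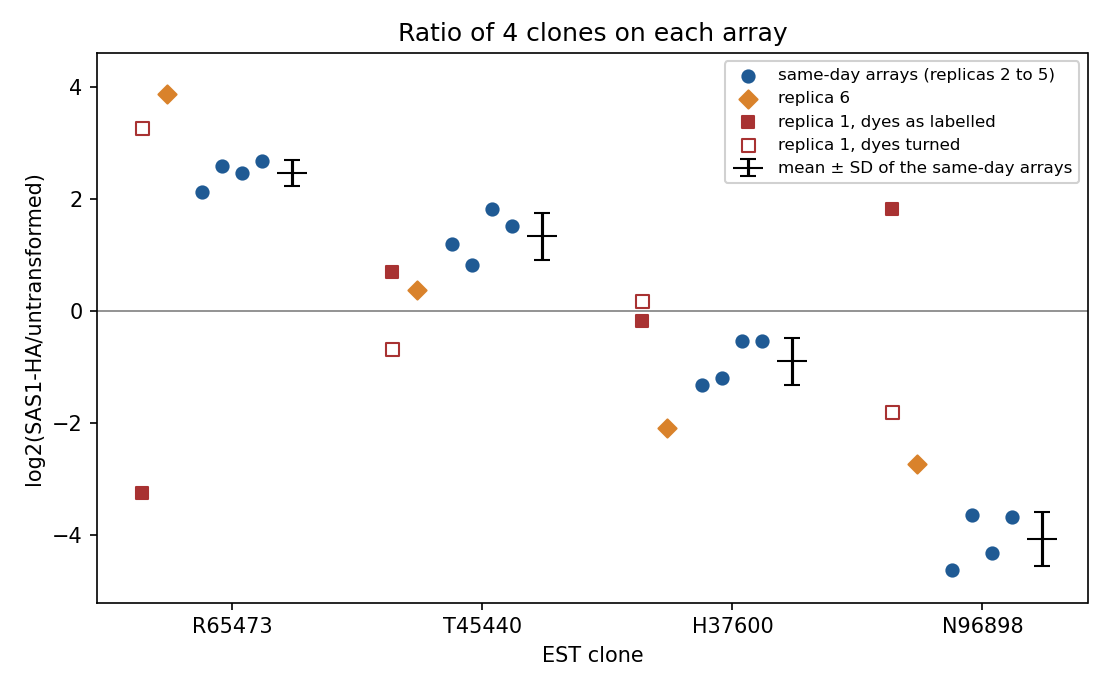
Log2(SAS1-HA/untransformed) of EST clones R65473, T45440, H37600 and N96898 on each array: circles for the 4 same-day arrays with their mean and SD, diamonds for replica 6, and squares for replica 1 with its dyes as labelled (filled) and turned (open). The same-day values of R65473 average 2.46 and those of N96898 -4.07, and replica 1 as labelled lies on the other side of 0 for both, at -3.25 and 1.81.

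The clones changed on the same-day arrays were compared with the earlier arrays, where the direction of replica 1 is not settled and both are given. Of the 980 clones higher by at least 2-fold, 54.2% were higher on replica 6 and 38.7% on replica 1 as labelled (61.3% turned), where 50% comes from chance. Of the 523 lower by at least 2-fold, 51.6% were lower on replica 6 and 47.4% on replica 1 as labelled (52.6% turned). The 228 clones that rose at least 4-fold had a median log2 ratio of 2.32 on the same-day arrays, 0.04 on replica 6, and -0.06 on replica 1 as labelled or 0.06 turned. The 50 clones that fell at least 4-fold had a median of -2.55 on the same-day arrays and -0.99 on replica 6, where 76.0% of them were lower. On replica 1 as labelled the median of these 50 clones was 1.29, and 30.0% were lower. With replica 1 turned it was -1.29, and 70.0% were lower.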

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

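All tests of the sign of replica 1, of dye bias, of slopes between pairs and of a smaller difference on the earlier arrays were chosen after the results were seen. The other splits of the arrays were planned. The tests of loess and of background correction were set down before their own results were seen, but on the same-day arrays, a comparison added after seeing the data. Of 14 measures compared over the 6 arrays, 5 had 1 array far from the others, where chance flags about 1 in 20 groups. Replica 6 had a median blank-spot intensity of 258.5 in the untransformed channel, with the next highest array at 69.1. It had 66 saturated spots, with the next highest at 23. On replica 6, 18.5% of the variance of the log2 ratio lay between blocks of the array, with the next highest at 6.8%. Replica 1 as labelled stood apart for N96898, at 1.81 with the nearest array at -2.72, and for R65473, at -3.25 with the nearest array at 2.12, on the log2 scale. Both rest on the dye label of replica 1, and with it turned the values are -1.81 and 3.25. R65473 was chosen for its values and N96898 as the largest same-day fall, so the place of neither here is independent.

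Replicas 1 and 6 carry opposite dyes by their labels and ran opposite to each other. Over the 100 clones that changed most on the same-day arrays, Cy5/Cy3 on replica 1 correlated at 0.59 (95% interval 0.45 to 0.71) with the same-day ratio of SAS1-HA to untransformed, replica 6 at 0.56 and their mean at 0.59 (permutation p 1.00e-04, the smallest that 10000 permutations can give), though the sign was the same for 71% of the clones on replica 1 and 59% on replica 6, and interval and p treat clones as independent. The correlation of the mean rests on the step between 27 falls, with medians of -1.39 on replica 1 in Cy5/Cy3 and -1.66 on replica 6, and 73 rises, with medians of 0.08 and 0.03, and within these sets it was 0.10 (-0.30 to 0.46) and -0.03 (-0.26 to 0.20). A wrong dye label on replica 1 may account for the falls, but dye bias shared by clones of the same gene stays open too, since the clones are not named. Over all clones the mean Cy5/Cy3 of replicas 1 and 6 correlated at 0.15 with the same-day dye coefficient. Given that coefficient, the correlations over the 100 clones were 0.55 on replica 1 and 0.52 on replica 6. Both values leave dye bias open, as it can differ between labelling sessions.

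No clone passed over 6 arrays while 5873 passed over the 4 same-day arrays. Turning replica 1 gave 2415 clones, but leaving out replica 1 gave 2497 and leaving out replica 6 gave 2556, so the count does not single out the sign of replica 1. Over the 100 clones, the mean of replicas 1 and 6 with replica 1 turned had a slope of 0.21 on the same-day ratio. The 95% interval was 0.15 to 0.27. The slope was 0.01 as labelled and 0.22 for replica 6 alone, again set by the step between falls and rises. Clones chosen in the same way on 1 same-day pair had slopes of 0.88 and 0.95 on the other pair. Spread between same-day pairs therefore does not give so low a slope. Both pairs share the scanning day and may share RNA, however. Choosing ratios that are large only on that day or in those plants could still lower the slope on the earlier arrays. A smaller difference between the lines on the earlier arrays, not of 1 size for falls and rises, which may come from other plants, stays open, and plants and scanning day could not be parted. Of the 10 splits of the 6 arrays into 3 and 3, 10 gave as many clones as the real one, with 0 in the real split and 0 as the highest of the others, which decides nothing, since no split can fall below 0 and 10 splits are too few for a share under 0.05.

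Rises outnumbered falls among the clones changed at least 2-fold on the same-day arrays, at 65.2%. Without loess, by median centring, rises were 67.2% (95% interval 64.8% to 69.6%), and without background correction 64.1% (61.7% to 66.5%). The excess stayed, so neither step alone accounts for it. The intervals in this paragraph treat clones as independent, which they are not, and do not measure the spread between arrays. In the authors' table the share was 56.6% (54.1% to 59.0%), lower than in the other processings, and the cause was not tested, since that table differs in more than 1 step. Without background correction 27.7% of the brightest and 5.6% of the dimmest of 5 equal groups of clones still changed at least 2-fold. A difference between the lines stays open as a hypothesis for the excess of rises, as does a cause tied to the scanning day, which was not tested.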

How the results depend on the processing

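The same-day fit with all its alternatives, turning replica 1, pair means and the blank-spot filter were added after seeing the data, and the other alternatives were planned. Over 6 arrays the count of clones past the threshold stayed at 0 under other backgrounds and normalizations, the authors' table, ignored spots kept, both filters, no dye term, a 2-fold minimum, scan day as a random block (correlation 0.71) and pair means. It became 6719 (3349 higher, 3370 lower) with array weights. These were 0.23 and 0.21 for replicas 1 and 6 and 1.34 to 4.4 for the same-day arrays, on which this count mainly rests. With replica 1 turned the count was 2415 (1393 higher, 1022 lower). Leaving out 1 array gave 0 to 2556 (0 to 1472 higher, 0 to 1112 lower), above 0 only without replica 1 (2497) or 6 (2556). On the same-day arrays the count stayed between 4685 and 6134, with leaving out 1 array included, except for 1503 (980 higher, 523 lower) with a 2-fold minimum. In the authors' table the balance turned to 2694 higher and 3240 lower, from 2972 and 2901, and 2-fold rises were 56.6% of 2-fold changes, from 65.2%. Over 6 arrays the 4 named clones kept their sign under each alternative that measured them, but N96898 ran from -4.06 (array weights) to -1.86 (scan day block) and R65473 from 1.15 (scan day block) to 2.76 (replica 1 turned), with adjusted p over the 4 clones from 2.70e-05 to 0.9996. The correlation of replicas 1 and 6 was -0.69 with the blank-spot filter, -0.66 with plain background subtraction, -0.71 with print-tip loess and -0.67 in the authors' table. The mean correlation of same-day arrays of opposite orientation was 0.74, and 0.81 with print-tip loess and 0.68 with median centring. Where not given above, the cause was not tested. The filter on local background plus 2 SD removed 0 clones and tests nothing. The pair means over 6 arrays took replicas 1 and 6 as a further pair, though they share no scan day. As labelled these 2 arrays largely cancelled, with an SD of their mean of 0.236 against 0.708 for the same-day mean. The count of 0 from pair means was therefore nearly fixed in advance and adds little. Not run were median pixel values, clones averaged per gene, gene lists and serpin genes, which the files used here do not allow, and the image tag as a random block, for which limma gave no correlation from 4 arrays. Dim clones are limited by signal over the blank spots: the blank-spot filter keeps 10907 of 11926 clones over 6 arrays.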

Other observations

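The comparisons here were all chosen after the data were seen. Clones with large same-day falls and rises were followed on replicas 1 and 6. Replica 1 is given as Cy5/Cy3, since its direction is not settled. Of the 50 clones that fell at least 4-fold on the same-day arrays, 23 were lower by at least 2-fold on replica 6 and 0 were higher by as much. In Cy5/Cy3, 28 of the 50 were lower by at least 2-fold on replica 1 and 0 were higher, and 22 were lower on both arrays. Of the 228 clones that rose at least 4-fold, 5 were higher and 3 lower by at least 2-fold on replica 6, 2 were higher and 6 lower in Cy5/Cy3 on replica 1, and 2 were higher on both. Over all 11926 clones, 150 were higher and 197 lower by at least 2-fold in Cy5/Cy3 on both earlier arrays. The median log2 intensity was 11.3 for the falls and 13.4 for the rises. This intensity averages both lines over the 6 arrays, so the falls themselves lower it and the rises themselves raise it. The difference between falls and rises was not tested.

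Replicas 1 and 6 shared large Cy5/Cy3 ratios of their own. At least 2-fold on both, 347 clones had the same Cy5/Cy3 sign and 3 the opposite sign. Of the 347 clones, 67 were also past the threshold with at least a 2-fold change on the same-day arrays, against 1503 of all 11926 clones. Of these 67, 48 had the direction that replica 6 gave, and the 48 include the 22 falls given above.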
